A study of Mus musculus with 4 samples.

How the data were processed

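Expression was measured in 4 samples, 2 of Ly49+ (CD44+CD122+Ly49+) and 2 of Ly49- (CD44+CD122+Ly49-) CD8 T cells sorted from the spleen of wild-type B6 mice. Groups and replicate numbers were taken from the sample titles. Per the labels, total RNA was extracted with the RNeasy kit and biotin-labelled by the Affymetrix protocol. The values deposited by the authors were linear intensities per probe set, read as such from the values, which were never 0 or negative and ran from 8.32 to 43959. Their quartiles differed between arrays by at most 0.04 on the log2 scale, so the arrays had been brought to nearly the same distribution before deposit. The method that did this is not given in the sources used here. No scanner files were used here.

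Probe sets were named through the platform annotation of 2016. Of 45101 probe sets, 34945 had 1 gene symbol, 932 had several, 9160 were not listed in that annotation and 64 were control probe sets. Gene IDs of 34754 probe sets were matched to a RefSeq list of genes (assembly GRCm38.p6, used for names alone), which changed 0 symbols. For each of 18193 genes, the probe set with the highest mean over the 4 arrays was kept: 9183 genes had 1 probe set and 9010 several. Of the chosen probe sets, 590 had names ending in _x_at and 925 in _s_at, the kinds that may also detect other transcripts, which are called open to cross-hybridisation. Probe sets with several genes or none were left out of the gene tests. Of 421 changed genes with further probe sets, 109 had one with a change of the opposite sign, and in 11 of these it had an unadjusted p under 0.05.

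Intensities were transformed to log2(intensity + 16) with no further normalization, so fold changes are on that scale and understate the change of dim genes. Differences were tested with limma 3.58.1 in R 4.3.3 (lmFit and eBayes with a trend of the spread on the expression level, group as the only term, 2 residual and 6.70 prior degrees of freedom), with Benjamini-Hochberg adjustment and a threshold of 0.05. Tables were read and joined with the R package data.table (version 1.17.8). Genes with at least a 2-fold difference whose groups did not overlap were counted as well. For 30 gene lists, 515 of 598 entries were measured, and the 28 lists with at least 5 measured genes were tested with limma's camera (preset correlation 0.01), adjusted over the 28 lists. An estimated correlation and fry were run beside it. Camera called 12 lists, 10 upward and 2 downward, and with an estimated correlation it called 0 (4 lists at an unadjusted p under 0.05), with a smallest adjusted p of 0.267, while fry called 7, of which 5 were among the 12. The lists, tests, alternatives and rule for named genes were fixed before the data were examined.

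The named genes were the 12 with the largest positive and the 12 with the largest negative change among those past the threshold, Ikzf2, Foxp3, the sort genes, the measured Klra genes, and up to 4 members with the smallest p of each list. Further members of the lists are named in the text where they bear on a group, and were chosen after their values were seen. The median log2 fold change of all genes was -0.04, and quantile normalization gave -0.03.

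The tests were tried on simulated data for this comparison, with the 18193 genes and 2 arrays per group and 200 genes changed. Of the simulated changes of 0.5 on the log2 scale, 67.2% of 67 genes were recovered, and all 67 genes changed by 1 and all 66 changed by 2 were recovered. Of 191 genes called, 13 (6.81%) were false, and camera called 0 of 20 unchanged lists. The simulated spread was drawn from the spread that limma had fitted, with independent normal noise, so the model of the test held by design. These rates are therefore not the error rate of the calls in the data. The simulated genes varied independently and shared no replicate effect, so this trial cannot show how camera treats lists of correlated genes. In the data, the estimated correlation was 0.23 for the cell cycle list, 0.38 for the interferon list and 0.72 for the immediate-early list. The number of arrays limits the precision. Alternatives were quantile normalization, pseudocounts of 1 and 64, the brighter genes alone, the mean of a gene's probe sets, no probe sets open to cross-hybridisation, no trend or a robust estimate of the spread, a replicate block, an adjusted p under 0.1, and leaving out each array, where the lone array of a group was assumed to vary like the other group.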

Results

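RNA from CD8 T cells sorted from the spleens of wild-type B6 mice was measured on 4 Affymetrix mouse expression arrays. The labels give 2 groups of 2 arrays. The Ly49+ group was sorted as CD44+CD122+Ly49+ cells, which the labels call CD8 Treg, and the Ly49- group as CD44+CD122+Ly49- cells, called conventional memory cells. Ly49 molecules, encoded by the Klra genes, are receptors for MHC class I best known from natural killer (NK) cells. The comparison addresses how the expression programs of these cell types differ, and the series title names Helios, the transcription factor encoded by Ikzf2. The labels do not say that the replicates came from separate animals, so p-values measure only the spread between these samples, which may be technical. Array medians of the deposited intensities lay between 188.5 and 190.4, the pairwise Pearson correlation across all probe sets between 0.996 and 0.998, and the number of arrays limits the precision. Of 45101 probe sets, the brightest probe set of each of 18193 genes was tested with limma.

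The largest rises in Ly49+ cells were in genes of NK-cell receptors, in Ikzf2 and in Spry2, an inhibitor of growth-factor signalling. Klra7, which encodes a Ly49 receptor, was 9.71-fold higher in Ly49+ than in Ly49- cells, at an intensity of 8932 ± 52.8 against 905 ± 7.17 (mean ± SD, 2 arrays each; log2 fold change 3.28 ± 0.05 SE, limma adjusted p = 1.2e-08). Spry2 was 6.58-fold higher, at 7828 ± 555 against 1175 ± 62.4 (adjusted p = 1.8e-07). Its other probe set, dim at 70.1 against 44.4, did not pass (adjusted p = 0.073 with each probe set tested on its own). Both of those means lay below the highest bacterial control (70.3), so no size is given for that probe set. Hhex, a homeobox transcription factor, rose 3.05-fold, Gpat3, an enzyme of triglyceride synthesis, 3.02-fold, and Styk1, a receptor-like kinase, 2.97-fold. The largest fall was in Gzmk, which encodes the protease granzyme K, 4.55-fold lower at 190 ± 29.8 against 920 ± 136 (log2 fold change -2.19 ± 0.14 SE, adjusted p = 1.2e-04). Klrg1, a receptor of terminally differentiated T and NK cells, was 3.78-fold lower, the inhibitory receptor gene Ctla4 2.71-fold and Nrn1 2.40-fold lower. The membrane protease gene Tmprss13 fell too, but its Ly49+ mean of 51.2 lay below the highest bacterial control (70.3), so no exact fold is given.

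In all, 728 of 18193 genes changed, 352 higher and 376 lower in Ly49+ cells, and 3284 genes had an unadjusted p under 0.05. Among them, 61 genes differed at least 2-fold with no overlap of the groups, 44 higher and 17 lower. Without regard to size, 48.4% of all genes had no overlap, where chance gives 33.3%. The other genes among the 12 with the largest rises were Klra8, Klre1, Klra5, Klrc2, the gamma-delta T-cell receptor segment Trgv1 (log2 fold change 1.56, adjusted p = 1.2e-04) and 6330407A03Rik (1.36, adjusted p = 0.0032). The other genes among the 12 with the largest falls were Gzmb (-1.21), St8sia1 (-1.13), Bambi-ps1 (-1.12), Igha (-1.11), Stc2 (-1.08), Dsg2 (-1.06) and the immunoglobulin segment Igkv6-20, with adjusted p between 1.2e-04 and 0.019. No size is given for Igkv6-20, and its place among the 12 is uncertain, since its Ly49+ mean of 44.3 lay below the highest bacterial control (70.3), as did that of Tmprss13. Klra, Klrc, immunoglobulin and T-cell receptor segments belong to families of near-identical genes, so probe sets for them may have read more than 1 member. Fits that left out 1 array called 289 genes without Ly49+ replicate 1, 261 without Ly49+ replicate 2, 115 without Ly49- replicate 1 and 107 without Ly49- replicate 2, and 74 of the 728 genes passed in all 4 of these fits. Igkv6-20 missed the threshold without Ly49+ replicate 1 (adjusted p = 0.11), Ly49+ replicate 2 (0.060) or Ly49- replicate 2 (0.094), Dsg2 without Ly49- replicate 2 (0.066), and 6330407A03Rik without Ly49- replicate 1 (0.075) or 2 (0.056).

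**Figure D1:**
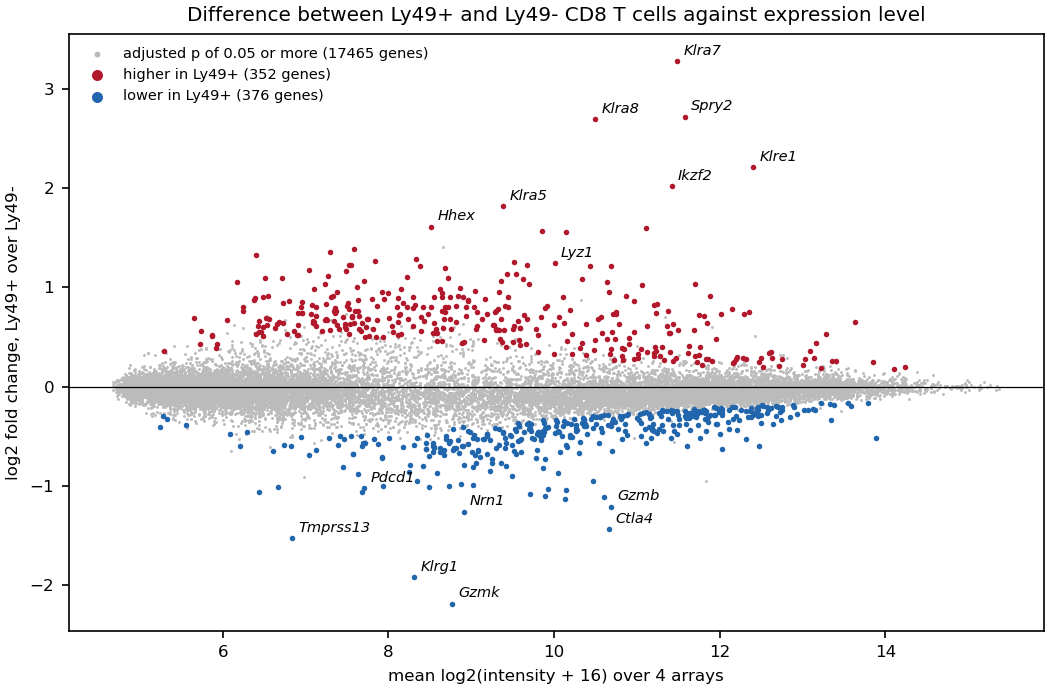
Difference between Ly49+ and Ly49- cells for 18193 genes. The x axis is the mean log2(intensity + 16) over the 4 arrays and the y axis the log2 fold change of Ly49+ over Ly49-. Red points are the 352 genes higher and blue points the 376 genes lower past adjusted p 0.05, led by Klra7 at 3.28 and Gzmk at -2.19.

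Ikzf2 was 4.04-fold higher in Ly49+ cells, at an intensity of 5499 ± 42.6 against 1351 ± 131 (log2 fold change 2.02 ± 0.07 SE, adjusted p = 2.3e-06). The other probe sets of the gene gave log2 fold changes of 1.45 and 2.38. No other gene of the Ikaros family of lymphoid transcription factors passed the test. Ikzf3 differed by 0.09, Ikzf4 by -0.08 and Ikzf1 by 0.02 on the log2 scale, with adjusted p of 0.39, 0.84 and 0.87. Of the 5 members measured, 1 was higher, none was lower and 4 did not pass, with the same counts adjusted over the list alone. The list was called higher by limma's camera (adjusted p = 0.0061) on the rise of Ikzf2, and not with an estimated correlation (adjusted p = 0.48 with an estimated correlation). The adjusted p of the list was 0.079 without Ly49+ replicate 1, where its median was -0.00.

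Ly49 receptor genes, on which the cells were sorted, were called higher as a list by camera (adjusted p = 1.2e-17, and adjusted p = 0.27 with an estimated correlation) and are a check of the sort, not a finding. Of 7 measured, 5 were higher and 2 did not pass, or 6 higher adjusted over the list alone. Klra8 rose 6.48-fold and Klra5 3.53-fold. Klra16 was called higher at 106 against 49.5 and Klra2 at 28.4 against 18.7, but the lower Klra16 mean and both Klra2 means lay below the highest bacterial control (70.3), so their size is not given. The Klra1 and Klra17 means lay below it in both groups and did not pass (adjusted p = 0.093 and 0.36). Klra7, Klra8 and Klra16 were read by probe sets open to cross-hybridisation, and probe sets shared by Klra22 and Klra1 or by Klra9 and Klra3 were higher too (adjusted p = 0.0020 and 0.0028, each probe set tested on its own). Klra16 missed the threshold without Ly49- replicate 2 (adjusted p = 0.064), and Klra2 without any 1 of the arrays (0.088 without Ly49+ replicate 1, 0.23 without Ly49+ replicate 2, 0.13 without Ly49- replicate 1 and 0.27 without Ly49- replicate 2).

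Genes of other NK-cell receptors and their signalling adaptors rose as well, with Klrg1 moving the other way. Klre1 was 4.63-fold higher (intensity 11670 ± 54.5 against 2508 ± 84.7, adjusted p = 6.5e-08), Klrc2 2.61-fold, Cd244a 2.40-fold, the adaptor Fcer1g 2.32-fold, Klrc1, which encodes the inhibitory receptor NKG2A, 1.88-fold, and Klrk1, which encodes the activating receptor NKG2D, 1.69-fold. The adaptor Tyrobp (log2 fold change 0.61), Cd160 (0.48) and Fcgr3 (0.33) also rose. Klrc3 and Klrb1a were called higher, with no size given since their Ly49- means of 46.5 and 52.4 lay below the highest bacterial control (70.3). Probe sets shared by Klrc3 and Klrc2 or by Klrb1b and Klrb1c were higher too (adjusted p = 0.0074 and 0.0044, each probe set tested on its own). Klrd1, the partner chain of NKG2A, differed by 0.14 (adjusted p = 0.18), and Ncr1, a receptor of most NK cells, was read below the highest bacterial control in both groups. Klrg1 fell, at an intensity of 151 ± 52.8 against 620 ± 216. Of 22 measured genes, 11 were higher, 1 was lower and 10 did not pass, or 13 higher and 3 lower adjusted over the list alone. The list passed camera at an adjusted p of 1.7e-14 (adjusted p = 0.27 with an estimated correlation). On the same arrays, the marker lists of myeloid and B cells had medians of 0.47 and 0.32. In the B-cell list MHC class II genes rose, while Cd79b fell and Ighm did not pass. Without Ly49- replicate 2, Klrg1 had an adjusted p of 0.091, and it had 0.051 without a trend of the spread and 0.14 with a robust spread.

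**Figure D2:**
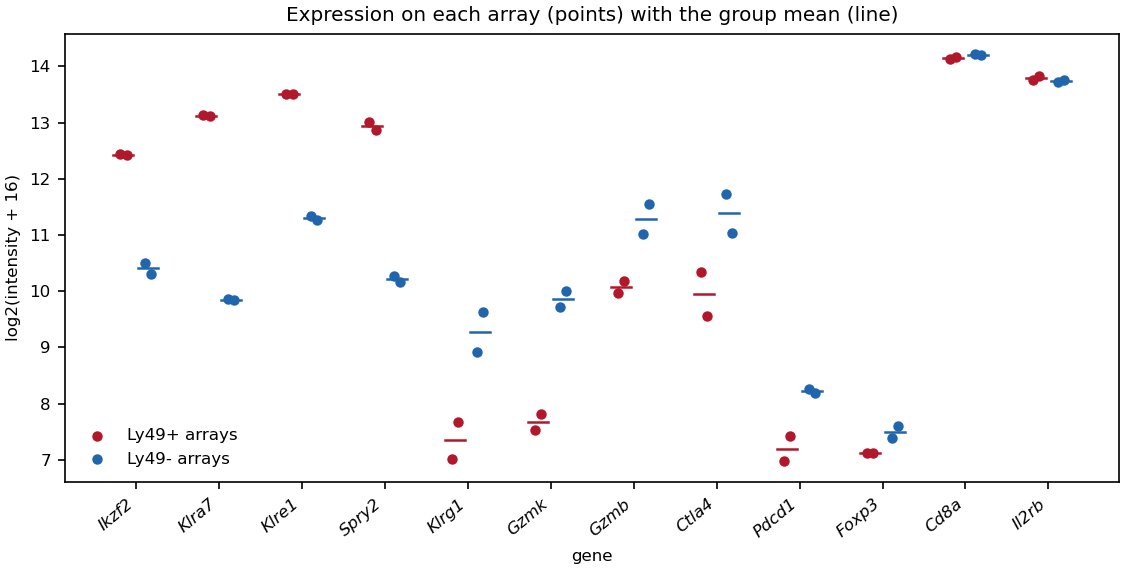
Level of 12 named genes on each array. The y axis is log2(intensity + 16), each point is 1 array (red Ly49+, blue Ly49-), and each line is the mean of a group's 2 arrays. Ikzf2, Klra7, Klre1 and Spry2 lie higher on both Ly49+ arrays and Gzmk and Klrg1 lower, while the Foxp3 (adjusted p = 0.14), Cd8a (0.40) and Il2rb (0.54) differences did not pass.

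Among cytotoxic effector genes, 2 granzymes were lower in Ly49+ cells and the other genes did not pass. Gzmk fell 4.55-fold, and Gzmb, which encodes the apoptosis-inducing protease granzyme B, was 2.31-fold lower at 1070 ± 116 against 2533 ± 661 (log2 fold change -1.21 ± 0.15 SE, adjusted p = 0.0038). Gzma differed by -0.95 (adjusted p = 0.051), the perforin gene Prf1 by -0.08 (0.45) and Tnfsf10, which encodes the death ligand TRAIL, by 0.17 (0.26). Of 19 measured genes, none was higher, 2 were lower and 17 did not pass, or 3 lower adjusted over the list alone. Camera gave an adjusted p of 0.76 (0.83 with an estimated correlation), and the mean of -0.19 had the opposite sign to the median of 0.01 and the camera direction. Gzmb had an adjusted p of 0.11 with a robust spread.

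Inhibitory receptor genes moved in both directions. Cd244a (log2 fold change 1.26), Havcr2 (0.82), which encodes TIM-3, and Cd160 (0.48) rose in Ly49+ cells. Cd244a is also in the NK-cell marker list, which had a median of 0.58 on the same arrays, where the myeloid median was 0.47. Klrg1 (-1.92), Ctla4 (-1.44), Pdcd1 (-1.02), which encodes PD-1, and Lag3 (-0.71) fell. Ctla4 intensities were 1008 ± 378 against 2740 ± 927 (adjusted p = 0.018). Of 15 measured genes, 3 were higher, 4 were lower and 8 did not pass, or 4 higher and 5 lower adjusted over the list alone. Camera gave an adjusted p of 0.55 (0.82 with an estimated correlation), with an upward direction against a median of -0.01 and a mean of -0.16. Without Ly49- replicate 1 the adjusted p was 0.16 for Ctla4, 0.11 for Pdcd1, 0.085 for Lag3 and 0.070 for Havcr2, and without Ly49- replicate 2 it was 0.081, 0.12, 0.11 and 0.064. Ctla4 had 0.068 without Ly49+ replicate 2, 0.12 without a trend and 0.36 with a robust spread, and Lag3 had 0.068 without Ly49+ replicate 1.

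Genes associated with follicular helper T cells were lower in 3 cases, Pdcd1, Cd200 (log2 fold change -0.95) and Slamf1 (-0.77), and higher in 1, the transcription factor Maf (0.58). Cxcr5, the receptor that guides cells to B-cell follicles, differed by -0.26 (adjusted p = 0.15). Of 15 measured genes, 11 did not pass, and 3 were higher and 6 lower adjusted over the list alone. Camera gave a downward direction with an adjusted p of 0.17 (0.70 with an estimated correlation). Without Ly49- replicate 1, Cd200 had an adjusted p of 0.057, Slamf1 0.058 and Pdcd1 0.11. Pdcd1 had 0.12 without Ly49- replicate 2, and Maf had 0.079 without Ly49+ replicate 1, 0.084 without Ly49+ replicate 2, 0.10 without Ly49- replicate 2, 0.051 without a trend and 0.21 with the mean of its probe sets.

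The signature of CD4 regulatory T cells was not called as a group. Besides Ikzf2, Swap70 rose (log2 fold change 0.71), and Ctla4 (-1.44), Nrp1 (-0.9997), Lag3 (-0.71) and Capg (-0.36) fell. Foxp3, the defining transcription factor of CD4 regulatory T cells, was read at 123 ± 0.263 against 165 ± 19.95 (log2 fold change -0.38 ± 0.12 SE, adjusted p = 0.14). Of 27 measured genes, 2 were higher, 4 were lower and 21 did not pass, or 2 higher and 7 lower adjusted over the list alone. Camera gave an adjusted p of 0.97 (0.97 with an estimated correlation) with an upward direction, against a median of -0.08 and a mean of -0.05. Without Ly49- replicate 1, Ctla4 had an adjusted p of 0.16, Swap70 0.087, Lag3 0.085 and Nrp1 0.055. Swap70 had 0.065 without Ly49+ replicate 2 and 0.072 without Ly49- replicate 2, Lag3 had 0.068 without Ly49+ replicate 1 and 0.11 without Ly49- replicate 2, and Ctla4 had 0.068 without Ly49+ replicate 2 and 0.081 without Ly49- replicate 2. None of the other sort genes differed past the threshold, with log2 fold changes of -0.06 for Cd8a (adjusted p = 0.40), -0.07 for Cd8b1 (0.30), 0.16 for Cd44 (0.21) and 0.05 for Il2rb, which encodes CD122 (0.54).

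Of 31 measured cell cycle genes, 20 fell in Ly49+ cells, none rose and 11 did not pass, or 28 were lower adjusted over the list alone. The median log2 fold change was -0.44. On the same arrays, the myeloid, B-cell and NK-cell marker lists had medians of 0.47, 0.32 and 0.58. The 26 measured genes of the T-cell receptor complex and its signalling had a median of -0.04, with a lowest value of -0.17. That argues against a lower share of T-cell RNA as the source of a fall of this size. The 3' to 5' ratio of Actb was 1.26 and 1.29 on the Ly49+ and 1.37 and 1.34 on the Ly49- arrays. The 5' probe set of 18S ribosomal RNA read 878 and 669 against 471 and 339, while its middle probe set read 16035 and 15592 against 17085 and 13373. Ccnb2 (log2 fold change -0.72), Tpx2 (-0.68), Nusap1 (-0.57), Ccna2 (-0.53), Birc5 (-0.48) and Mki67 (-0.44), which act in mitosis or mark cycling cells, were among those that fell. The list passed camera with an adjusted p of 3.35e-21 (adjusted p = 0.27 with an estimated correlation). Without Ly49- replicate 2, the adjusted p was 0.058 for Tpx2 and Nusap1, 0.057 for Ccna2 and 0.054 for Birc5, and it was 0.064 for Tpx2 without Ly49- replicate 1. With the mean of all probe sets of a gene, it was 0.13 for Tpx2 and 0.19 for Nusap1.

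Of 24 measured genes of the type I interferon response, 4 fell, with a list median of -0.13. Oas2 (log2 fold change -0.49), Isg20 (-0.42), Oasl2 (-0.38) and Bst2 (-0.32), all induced by interferon, were those that fell, 20 did not pass and none rose, or 10 were lower adjusted over the list alone. The list passed camera with an adjusted p of 1.0e-05 (adjusted p = 0.48 with an estimated correlation), and fry gave 0.096. With all arrays kept, the limma adjusted p without a trend of the spread was 0.051 for Oas2, 0.062 for Oasl2 and 0.076 for Bst2. For Oasl2 it was 0.059 after quantile normalization and 0.056 with a pseudocount of 64. The myeloid, B-cell and NK-cell marker medians of 0.47, 0.32 and 0.58 were on the same arrays. None of these 4 genes passed when any 1 array was left out, with an adjusted p for Oas2 of 0.12 without Ly49+ replicate 1, 0.063 without Ly49+ replicate 2, 0.079 without Ly49- replicate 1 and 0.16 without Ly49- replicate 2. In the same order, Isg20 had 0.10, 0.088, 0.087 and 0.12, Oasl2 0.26, 0.13, 0.14 and 0.23, and Bst2 0.11, 0.080, 0.080 and 0.11.

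Naive and central memory genes fell in 4 cases. Igfbp4 fell by 0.95 on the log2 scale and was read by a probe set that may also detect other transcripts, Dapl1 fell by 0.52, Cd55 by 0.39 and the interleukin-6 receptor gene Il6ra by 0.28. Of 20 measured genes, none rose and 16 did not pass, with the same counts adjusted over the list alone. Camera gave an adjusted p of 0.16 (0.48 with an estimated correlation) with a downward direction. The list passed without Ly49- replicate 2 (adjusted p = 0.030), and Cd55 and Il6ra did not pass when any 1 array was left out (adjusted p of 0.058 and 0.069 without Ly49+ replicate 1, 0.052 and 0.063 without Ly49+ replicate 2, 0.075 and 0.065 without Ly49- replicate 1, and 0.058 and 0.068 without Ly49- replicate 2). Without a trend of the spread, Il6ra had 0.096.

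Of the effector and memory transcription factors, Maf (log2 fold change 0.58) and Irf8 (0.55) rose and Zbtb32 (-0.9992) fell, and Eomes, which maintains memory CD8 T cells, differed by 0.14 (adjusted p = 0.12). Of 23 measured genes, 20 did not pass, and the counts adjusted over the list alone were the same. The list had a median of 0.10 and passed camera with an adjusted p of 0.0026 (adjusted p = 0.38 with an estimated correlation), and fry gave 0.40. Irf8 is also in the dendritic-cell and NK-cell marker lists, and the myeloid, B-cell and dendritic-cell lists had medians of 0.47, 0.32 and 0.21 on the same arrays. Without Ly49- replicate 1, Irf8 had an adjusted p of 0.091 and Zbtb32 of 0.064. Irf8 had 0.063 without Ly49+ replicate 2 and 0.076 without Ly49- replicate 2, and Maf had 0.079 without Ly49+ replicate 1, 0.084 without Ly49+ replicate 2 and 0.10 without Ly49- replicate 2.

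Among cytokine and chemokine genes, Ccl3 (log2 fold change 1.04), Csf2 (0.80), which encodes GM-CSF, Xcl1 (0.43) and Ccl5 (0.20) rose, none fell and 20 of 24 did not pass, or 5 were higher and 1 lower adjusted over the list alone. The list lay at the threshold of camera with an adjusted p of 0.0497 (adjusted p = 0.43 with an estimated correlation), and its median of -0.04 had the opposite sign to its mean of 0.08. Ccl3 is also in the NK-cell marker list, which had a median of 0.58 on the same arrays. The list had an adjusted p of 0.062 after quantile normalization, 0.061 with a pseudocount of 64, 0.052 without probe sets open to cross-hybridisation, 0.46 with fry, 0.16 without Ccl3, its largest member, 0.29 without Ly49+ replicate 1 and 0.083 without Ly49- replicate 1. Leaving out an array ended calls too: without Ly49- replicate 1 the adjusted p was 0.076 for Csf2, 0.057 for Ccl3, 0.067 for Xcl1 and 0.067 for Ccl5, without Ly49+ replicate 1 it was 0.057 for Ccl3, 0.16 for Xcl1 and 0.080 for Ccl5, without Ly49+ replicate 2 it was 0.053 for Csf2 and 0.13 for Ccl5, and without Ly49- replicate 2 it was 0.16 for Ccl3, 0.22 for Xcl1 and 0.093 for Ccl5. With all arrays kept, it was 0.10 for Ccl3, 0.15 for Xcl1 and 0.19 for Ccl5 without a trend of the spread, 0.31 for Ccl3 and 0.15 for Xcl1 with a robust spread, and 0.052 for Xcl1 with the mean of its probe sets.

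Chemokine receptor and integrin genes moved both ways. Xcr1 (log2 fold change 0.95), Itga1 (0.85), Itga2 (0.64) and Ccr2 (0.30) rose and Cx3cr1 (-0.81), Itgb3 (-0.39) and Itgb7 (-0.20) fell, and 24 of 31 did not pass, or 5 were higher and 3 lower adjusted over the list alone (camera adjusted p = 0.97, 0.98 with an estimated correlation). Xcr1 is also in the dendritic-cell and Itga2 in the NK-cell marker list, and on the same arrays the dendritic-cell, NK-cell and myeloid lists had medians of 0.21, 0.58 and 0.47. Without Ly49- replicate 1 the adjusted p was 0.057 for Xcr1, 0.070 for Itga1, 0.081 for Cx3cr1 and 0.057 for Itgb3, without Ly49- replicate 2 it was 0.072, 0.060, 0.080 and 0.072, and without Ly49+ replicate 2 it was 0.054 for Itgb3. With the mean of a gene's probe sets it was 0.093 for Cx3cr1 and 0.067 for Itgb3.

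Of cytokine receptor genes, Csf2rb, a shared chain of the GM-CSF receptor, rose (log2 fold change 0.81), Tgfbr3 (-0.82) and Il6ra (-0.28) fell, Il4ra differed by -0.19 (adjusted p = 0.080) and 22 of 25 did not pass, or 1 was higher and 4 lower adjusted over the list alone (camera adjusted p = 0.55, 0.92 with an estimated correlation). The mean of this list, -0.00, had the opposite sign to its median and its camera direction. Tgfbr3 was also the member of the TGF-beta pathway that fell, while Smurf1 (-0.33, adjusted p = 0.056), Tgfb2 (-0.22, 0.31) and Skil (-0.07, 0.44) did not pass. In that list none rose and 17 of 18 did not pass, or 2 were lower adjusted over the list alone (camera adjusted p = 0.92, 0.95 with an estimated correlation). Without Ly49- replicate 1 the adjusted p was 0.057 for Tgfbr3, 0.10 for Csf2rb and 0.065 for Il6ra, and without Ly49- replicate 2 it was 0.067, 0.051 and 0.068. Without Ly49+ replicate 2 it was 0.091 for Csf2rb and 0.063 for Il6ra, without Ly49+ replicate 1 it was 0.069 for Il6ra, and without a trend it was 0.055 for Csf2rb and 0.096 for Il6ra.

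Apoptosis regulators held 2 genes that fell, Birc5 (log2 fold change -0.48), which also acts in mitosis, and the death receptor gene Fas (-0.27), while Bak1 (0.25, adjusted p = 0.072) and Birc3 (-0.16, 0.094) did not pass. None of the 19 measured rose and 17 did not pass, or 1 was higher and 3 lower adjusted over the list alone. Camera gave an upward direction with an adjusted p of 0.76 (0.83 with an estimated correlation) and a median of 0.02, against a mean of -0.02. Birc5 had an adjusted p of 0.054 without Ly49- replicate 2. Fas had 0.059 after quantile normalization, 0.13 without a trend, 0.14 without Ly49+ replicate 1, 0.21 without Ly49+ replicate 2, 0.088 without Ly49- replicate 1 and 0.19 without Ly49- replicate 2.

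No gene passed, over all genes or adjusted over the list alone, among 26 genes of the T-cell receptor complex and its proximal signalling, 19 of the IL-2 and STAT5 pathway, 17 of glycolysis and 27 immediate-early and heat-shock genes. In the T-cell receptor list, Malt1 differed by 0.19 (adjusted p = 0.081), Trat1 by 0.48 (0.087), Cd247 by -0.12 (0.20) and Lat by -0.09 (0.22), and camera gave an adjusted p of 0.97 (0.98 with an estimated correlation) where fry gave 0.035 in the downward direction. Fry tests against 0, and the list median of -0.041 lay next to the median of all genes, -0.041. In the IL-2 list, Myc differed by 0.12 (adjusted p = 0.22), Stat5a by -0.10 (0.23), Pim2 by 0.10 (0.26) and Pim1 by 0.21 (0.28), and camera gave 0.056 (0.43 with an estimated correlation), 0.035 without Ly49+ replicate 2, 0.039 without Ly49- replicate 2 and 0.046 with only the brighter genes. In the glycolysis list, Ldha differed by -0.12 (adjusted p = 0.13), Hk2 by 0.32 (0.13), Pdk1 by -0.11 (0.13) and Pkm by -0.10 (0.22), and the camera direction was upward (adjusted p = 0.97, 0.98 with an estimated correlation) against a median of -0.03 and a mean of -0.01.

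The immediate-early and heat-shock list lay above 0 in 24 of 27 members and passed camera with an adjusted p of 3.4e-04 (adjusted p = 0.70 with an estimated correlation), and fry gave 0.68. Camera with a replicate block gave an adjusted p of 1.9e-11. Atf3, a stress-induced transcription factor, was read at 787 ± 654 against 297 ± 269 (log2 fold change 1.402 ± 0.67 SE, adjusted p = 0.32), Egr3 differed by 0.38 (0.13), Btg2 by 0.21 (0.15) and Fosl2 by 0.16 (0.16). By replicate number, Atf3 was read at 1249 on the first Ly49+ and 487 on the first Ly49- array, and at 324 and 106 on the second arrays. Egr1 differed more between replicate numbers than between groups, as it was read at 15121 on the first and 7109 on the second Ly49+ array, and at 14129 and 7003 on the Ly49- arrays. The list median changed from 0.07 to -0.04 without Ly49+ replicate 1 (adjusted p = 0.94) and to -0.11 without Ly49- replicate 2 (0.80).

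Marker lists of several other cell types of the spleen were called higher by camera on the Ly49+ arrays. The myeloid, B-cell and dendritic-cell lists each held genes that fell. Of 12 NK-cell markers, 7 rose, none fell and 5 did not pass, or 9 were higher and 1 lower adjusted over the list alone (median 0.58, camera adjusted p = 1.0e-13, adjusted p = 0.27 with an estimated correlation). They were Klre1, Cd244a, Fcer1g, Ccl3, Itga2, Tyrobp and Irf8, each of which is also in another of the lists. Of 19 myeloid markers, Lyz1 (log2 fold change 1.25), Lyz2 (1.13), Mpeg1 (0.83) and Csf1r (0.57) were among 10 that rose, the neutrophil genes S100a9 (-0.53) and S100a8 (-0.49) fell and 7 did not pass, or 11 were higher and 2 lower adjusted over the list alone (median 0.47, camera adjusted p = 1.6e-11, adjusted p = 0.27 with an estimated correlation). Of 18 B-cell markers, Cd22 (1.05) and the MHC class II genes H2-Ab1 (0.78), H2-Eb1 (0.73) and Cd74 (0.65) were among 6 that rose, Cd79b (-0.28) fell and 11, among them Ighm (-0.09, adjusted p = 0.37), did not pass, or 8 were higher and 1 lower adjusted over the list alone (median 0.32, camera adjusted p = 4.7e-12, adjusted p = 0.27 with an estimated correlation, fry 0.072). Of 12 dendritic-cell markers, Xcr1 (0.95) and Irf8 (0.55) rose, Bst2 (-0.32) fell, Zbtb46 differed by 0.43 (adjusted p = 0.084) and 9 did not pass, or 4 were higher and 1 lower adjusted over the list alone (camera adjusted p = 0.0075, adjusted p = 0.48 with an estimated correlation). The dendritic list had an adjusted p of 0.060 without Ly49+ replicate 2, 0.082 without Xcr1, 0.52 with only the brighter genes and 0.14 with fry, and Csf1r had 0.067 without Ly49- replicate 1 and 0.059 without Ly49- replicate 2. The Lyz1 probe set was open to cross-hybridisation, and without such probe sets its log2 fold change was -0.15 (adjusted p = 0.56).

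Other marker lists stayed below the threshold. In the gamma-delta and innate-like T-cell list, 5830411N06Rik (log2 fold change -0.63) and Cd163l1 (-0.30), members of the scavenger receptor family, fell, Sox13 differed by -0.17 (adjusted p = 0.46) and Zbtb16 by -0.20 (0.52), none of 6 rose and 4 did not pass, with the same counts adjusted over the list alone (camera adjusted p = 0.097, 0.69 with an estimated correlation). That list passed without Ly49- replicate 1 (adjusted p = 0.019), without Ly49+ replicate 2 (0.049) and with the mean of all probe sets (0.031), and Cd163l1 did not pass without Ly49+ replicate 1 (0.19), Ly49+ replicate 2 (0.080), Ly49- replicate 1 (0.067) or Ly49- replicate 2 (0.19), or without a trend (0.15). No gene passed among 7 CD4 T-cell markers, with Foxp3 at -0.38, Tnfrsf4 at -0.16, Il2ra at 0.18 and Izumo1r at 0.06, and none adjusted over the list alone (camera adjusted p = 0.97, 0.98 with an estimated correlation). No gene passed among 10 erythroid markers, with Hba-a2 at 0.13, Car2 at -0.31, Slc4a1 at 0.32 and Epb42 at 0.14, or 1 was higher and 1 lower adjusted over the list alone (camera adjusted p = 0.125, 0.48 with an estimated correlation, and 0.047 without Ly49- replicate 2). No gene passed among 9 platelet markers, with Clec1b at 0.61, and none adjusted over the list alone (camera upward, adjusted p = 0.66, 0.82 with an estimated correlation). Gp6 and Gp5 lay below the highest bacterial control (70.3) in both groups and Ppbp in Ly49- cells, so no size is given for them. Epb42 lay below it in Ly49- cells too. The platelet median of -0.04, which includes such genes, had the opposite sign to the mean of 0.04, and fry gave 0.0068 in the downward direction. The sex-linked genes Eif2s3y (0.05), Kdm5d (0.09), Uty (0.10) and Xist (-0.10) did not pass, and neither they nor the 4 sort genes were tested as a list, with no call adjusted over either list alone.

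**Figure D3:**
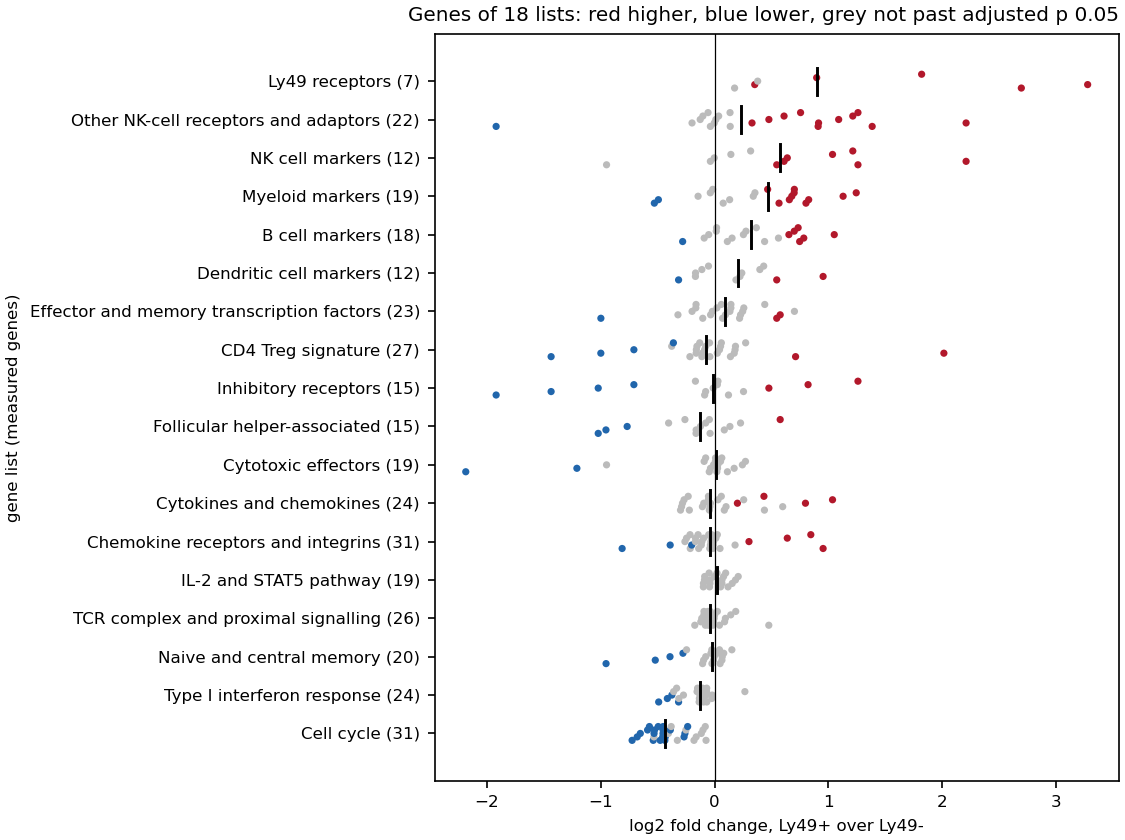
Log2 fold change of Ly49+ over Ly49- (x axis) for the measured genes of 18 lists (y axis, number of measured genes in brackets). Each point is 1 gene, red where higher, blue where lower and grey where not past adjusted p 0.05, and the black bar is the list's median. The Ly49 median lies at 0.90 and the cell cycle median at -0.44.

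Control probe sets gave a view of RNA quality. The ratio of the 3' to the 5' probe set of Gapdh lay between 1.70 and 1.75 on the 4 arrays, and that of Actb at 1.26 and 1.29 on the Ly49+ and at 1.37 and 1.34 on the Ly49- arrays. The probe set at the 5' end of the 18S ribosomal RNA separated the groups, at 878 and 669 on the Ly49+ and 471 and 339 on the Ly49- arrays, a difference of 0.94 on the log2 scale. The brighter probe set at the middle of that RNA did not, at 16035 and 15592 on the Ly49+ and 17085 and 13373 on the Ly49- arrays. Bacterial control probe sets read between 11.98 and 70.3, below the array medians.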

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

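The tests of the T-cell share, of NK cells and of less spike-in RNA were chosen after the result was seen, and those of macrophage RNA and of a dim patch before.

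Genes of spleen macrophages were higher on the Ly49+ arrays: in a list of 19 written after the myeloid markers had been seen, 17 rose, with a median log2 fold change of 0.64, led by Spic (1.26), Mertk (1.09) and Cd163 (1.08), while Vcam1 was read at 5324 ± 534 against 3193 ± 27.4 and C1qb at 4572 ± 364 against 2930 ± 36.9. A lower share of CD8 T cells with every other cell type higher alike was not decided. S100a9 fell (log2 fold change -0.53, adjusted p = 0.0082) and so did S100a8 (-0.49, adjusted p = 0.029), which goes against it for these genes alone. Both were in the myeloid list seen before this test was chosen. The 10 neutrophil genes as a set had a median of -0.11 within a spread of 0.31 (median absolute deviation). Of them, 3 lay above 0 and 6 above the bacterial controls in Ly49- cells. The erythroid median, named in the same test, was 0.08 and the platelet median -0.04, with the platelet genes Gp5 and Gp6 read near background. Macrophage RNA carried in the sort, which selected CD8, CD44 and CD122, stays open as a hypothesis: a second list of 22 macrophage genes, not looked at before, had a median of 0.23, with 17 above 0, 7 higher and 1 lower, under the 0.3 set for that source and over the bound of 0.1 set against it. None of the genes of either macrophage list is in the lists fixed before the data were examined, and all 19 and 21 of the 22 lay above the bacterial controls in Ly49- cells too. Expression of such genes by Ly49+ T cells, a difference that the design names, was not tested.

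NK-cell receptor genes rose in Ly49+ cells, with Klre1 at 11670 ± 54.5 against 2508 ± 84.7. NK cells in the sorted population stay open as a hypothesis for the source: of 6 markers in the fixed NK-cell list that are not receptors of this pattern and were read above the bacterial controls, Ccl3, Irf8 and Itga2 rose and Gzma, Eomes and Kit did not pass, with a median of 0.43, a spread of 0.37 (median absolute deviation) and 5 above 0. All 3 that rose are also in other lists, and 10 abundant NK-cell transcripts, listed after the result was seen and without the markers that rose, had a median of -0.07, with 1 above 0, none higher and 3 lower: S1pr5 differed by -0.05, Klrb1f by -0.06, Prf1 by -0.08 and Nkg7 by 0.02, Klrg1 (-1.92), Gzmb (-1.21) and Cx3cr1 (-0.81) fell, Gzma (-0.95) did not pass, and Ncr1 and Klrb1b were read near background. These values decide nothing, since that choice of genes largely fixed their direction and T cells also express several of them. All 12 NK-cell markers fixed before had a median of 0.58. That median decides nothing either, since they include Klre1, Cd244a, Fcer1g and Tyrobp, which are part of the pattern itself. Klrb1b was near background by the probe set that names it alone. A probe set shared by Klrb1b and Klrb1c, outside the gene tests, was higher at 892 ± 49.9 against 371 ± 2.97. Its log2 fold change was 1.23 (adjusted p = 0.0044, each probe set tested on its own). The sort on CD8 would remove NK cells that lack it, while cross-hybridisation among Klr genes and a receptor program of the Ly49+ T cells themselves stay open too, the last as an untested hypothesis.

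Spike-in control probe sets of the first series, outside the gene comparison, were dimmer on the array of Ly49- replicate 1, by a median of -1.97 on the log2 scale against the mean of the other 3 arrays (1416 against 5181 to 5863). Less spike-in RNA on that array is argued against by the second series of probe sets for the same RNAs, which differed by 0.036. A dim patch that also lowered gene probe sets at least 2-fold is argued against by the 0 gene probe sets that were that far below each other array, where the other arrays had 3, 1 and 1. A patch that lowered them by less is not covered by this count. What dimmed the first series stays open, and no biological explanation was tested.

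Probe sets without a gene in the annotation also carried a signal: with each probe set tested on its own, 58 were higher and 13 lower in Ly49+ cells at an adjusted p under 0.05, with the largest rise at a log2 fold change of 1.79 and the largest fall at -1.35. The control probe set at the 5' end of the 18S ribosomal RNA was higher on the Ly49+ arrays by 0.94 on the log2 scale, with intensities of 878 and 669 against 471 and 339. It did not pass, as none of the 64 control probe sets did in the same test. The middle 18S probe set did not separate the groups, at 16035 and 15592 against 17085 and 13373.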

How the results depend on the processing

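The settings that tested each probe set on its own and that left out the largest member of each list were chosen after seeing the data. All 728 changed genes kept their direction in each fit that tested them, except 2 of 728 with the mean of a gene's probe sets and 2 of 710 without probe sets open to cross-hybridisation. The fits without a trend, with a robust spread and with a replicate block have the same fold changes as the main fit, so they could not change a direction. The fits that left out 1 array reused the others, so part of that agreement was built in. The Ikzf2 difference of 2.02 passed in each setting, between 1.95 and 2.04, and between 1.92 and 2.11 with 1 array left out. Of 74 named genes that passed besides Ikzf2, 53 gave the same call in each setting that kept all arrays, and 32 also with each array left out.

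The 728 changed genes became 371 (218 higher, 153 lower) without a trend of the spread, and 1256 at an adjusted p under 0.1, with 752 lower. Among the brighter genes alone, which tests fewer genes, 215 were higher and 353 lower (37.9% higher, against 48.4% of the 728). The 61 genes with at least a 2-fold difference and no overlap became 37 with a pseudocount of 64, which shrinks the change of dim genes, and 36 among the brighter genes. With 1 array left out, which leaves fewer samples, 107 to 289 genes changed, 77 to 189 higher and 30 to 110 lower, with the lowest counts without Ly49- replicate 2. Camera called 12 lists, or 0 with an estimated correlation, and fry called 7, of which 5 were among the 12. For the trend of the spread and the list tests, the cause was not tested. Quantile normalization gave 376 higher and 276 lower, and 514 of all probe sets tested on their own passed.

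Lyz1 changed from 1.25 to -0.15 without probe sets open to cross-hybridisation, where another probe set is read. The immediate-early and heat-shock median of 0.07 lay between -0.110 and 0.314 with 1 array left out, at -0.041 without Ly49+ replicate 1. The platelet list was upward with camera, at a median of -0.042, and downward with fry. For the immediate-early list, leaving out 1 array left the replicate numbers unequal between the groups. Early-activation genes followed those numbers. Egr1 was read at 15121 and 14129 on the arrays numbered 1 and at 7109 and 7003 on those numbered 2. Whether this accounts for the whole shift of that list was not tested. The platelet median lay next to the median of all genes, -0.041. Camera compares a list with the other genes and fry compares it with 0, so a shift of all genes enters fry alone. Whether that accounts for both directions of the platelet list was not tested.

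The replicate numbers were not taken as pairing in the main test, since the labels name no shared animal or day and there are 2 pairs. With a replicate block, 1527 genes changed (616 higher, 911 lower), among them all 728, and the gamma-delta list passed (adjusted p = 0.047). The deviations of same-numbered arrays had a correlation of 0.24 across all genes and 0.44 across the brighter genes. The main test, without the block, counted that shared part as spread. Signal over background limits the dim probe sets, as bacterial controls reached 70.3.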

Other observations

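The genes of this part and the test of feedback genes were chosen after their values were seen. Segments of the gamma T-cell receptor chain rose in Ly49+ cells, Trgv1 2.94-fold (1929 ± 114 against 648 ± 87.4) and Trgv4 1.82-fold (2684 ± 125 against 1469 ± 123, limma adjusted p = 5.5e-04), while the gamma-delta T-cell genes 5830411N06Rik (log2 fold change -0.63) and Cd163l1 (-0.30) fell and Sox13 differed by -0.17 (adjusted p = 0.46). Immunoglobulin genes did not move as one: Igha was 2.15-fold lower in Ly49+ cells (632 ± 14.0 against 1389 ± 237), while Ighm differed by -0.09 (adjusted p = 0.37) and Igk by 0.00 (adjusted p = 0.997). Ighm and Igk were bright in both groups, at 14015 against 14929 and at 18687 against 18682, where Cd8a was read at 18186 against 18931. The source of that immunoglobulin signal in the sorted cells was not tested.

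Several genes of early activation were read higher on both arrays numbered 1 than on both numbered 2. Nr4a1 was read at 5683 and 4770 on the Ly49+ and Ly49- arrays numbered 1 and at 1887 and 1559 on those numbered 2, Fosb at 10635 and 8129 against 4038 and 2593, and Ifng at 8418 and 7506 against 3245 and 3924.

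The rise of Spry2, a feedback inhibitor of ERK signalling, raised the hypothesis of a general rise of feedback genes of that pathway. Of 16 other such genes, Etv5 (log2 fold change 0.98, adjusted p = 0.0014) and Spry4 (0.67, 0.023) rose and none fell, and 8 lay above 0. Spry1 did not pass (adjusted p = 0.085), and no size is given since its Ly49+ mean of 62.2 lay below the highest bacterial control (70.3). The median of the 16 genes was 0.0069 with a spread of 0.22 (median absolute deviation), below the 0.3 set for a general rise, so the set as a whole did not show one. A rise of some members, such as Etv5 and Spry4, is not excluded. Members such as Egr1 (0.06 ± 0.36 SE) and Phlda1 (0.22 ± 0.33 SE) were too variable to show a rise of that size.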
